A study of Homo sapiens with 6 samples.

How the data were processed

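RNA-seq was carried out on 6 libraries of H460/PTX cells, a paclitaxel-resistant derivative of the human large-cell lung cancer line H460. Of these, 3 came from cells infected with a Control lentivirus and 3 from cells infected with a lentivirus carrying ALKBH5. Per the labels' protocols, total RNA was extracted with Trizol, ribosomal RNA was removed and libraries were made with a low-input kit. The labels number the replicates 1 to 3 in each group and do not say that they were separate cultures, so the p-values measure only the spread between these libraries, which may be technical.

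The authors deposited one table of raw read counts per Ensembl gene, per the file headers, with no normalization of the counts. The submitters' processing notes name cutadapt 1.9.3, HISAT2 2.0.4, HTSeq 0.9.1, edgeR 3.16.5 and the genome build hg19, without their roles or order. The gene annotation and the strand setting of the counting are not given in the sources used here. The table lists 16306 genes, 0 of them with a biotype other than protein coding, and the lowest summed count of a gene over the 6 libraries is 1. A further 6 per-sample columns, with the authors' normalized counts under repeated column names, were not used. Gene symbols were updated through the Ensembl identifiers, of which 15899 had a current symbol. Where a symbol differs from the file's name, the text gives the file's name at first use for the genes of the main comparison.

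Counts were tested as deposited with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr (12560 genes), scaled by TMM and fitted with the quasi-likelihood model with group as the only term. P-values were two-sided and adjusted by the Benjamini-Hochberg method over all tested genes, with a threshold of 0.05. Levels are given as CPM on TMM-scaled library sizes, as mean ± SD over 3 libraries, and standard errors (SE) belong to the log2 fold change. Library totals lay between 22003627 and 30097648 counts, so a level near 1 CPM rests on few reads and has a wide error. Replicate pairs were compared by a chi-square statistic of their counts over genes with a summed count of at least 20, and no pair agreed within sampling noise.

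A set of 29 gene lists was fixed before the data were examined, from the series title and general cell biology, and 980 of its 1059 entries were found in the table. The last 4 lists hold markers of other cell types. The 27 lists with at least 5 tested members were tested with camera (limma 3.58.1) at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. Beside it stand camera with an estimated correlation, and fry, which tests whether the members of a list move on balance one way. With only 6 libraries, camera with an estimated correlation has little power. For each list, members past the threshold were counted over all genes tested and also adjusted over the list alone. Whether a list held a larger share of changed genes than the other tested genes was tested with Fisher's exact test, two-sided and adjusted over the lists. That test does not match genes by level, although genes with more reads are called more readily. It also takes the genes of a list as independent, so its p-values can be too small.

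Named genes follow a rule fixed before the data were examined. It takes ALKBH5 and CEMIP, the members of the m6A machinery list, and the 8 genes with the largest log2 fold change in each direction. The latter needed an adjusted p under 0.05, a mean of at least 1 CPM and no overlap between the groups. In each list it takes up to 3 passing members with the smallest p in the majority direction and up to 2 in the other. The text names part of this set, and says where a gene was chosen after its values were seen. Some genes of this set and 1 block of the scan of neighbouring genes are not reported here.

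The alternatives fixed beforehand were DESeq2 size factors and upper-quartile scaling in the same fit, no filter, the DESeq2 1.42.0 Wald test, limma-voom, the replicate number as a block, a 2-fold minimum, and leaving out each library in turn. Alternatives on pseudocounts and low-value filters had been planned for a table without counts and did not apply. Chosen after seeing the data were an offset for GC content and transcript length, thinning of every library to the smallest total, tests of the KEGG and GO terms in the deposited annotation, and a scan of neighbouring genes. GC content and length came from the longest GENCODE 29 transcript, found for 15926 genes (97.7%). In the scan, 10610 tested genes with a mean of at least 2 CPM were ordered along the chromosomes, and medians of log2 fold changes were taken in windows of 25 genes. Windows were kept if they lay farther from 0 than the most extreme window in 95% of 1000 permuted gene orders. The order came from GENCODE 29 on GRCh38, a later build than the authors', and no coordinates were used.

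The fits were tested on simulated counts with the means and library sizes of the real libraries. Of genes changed by a log2 fold of 0.5, 1 and 2, edgeR recovered 56.7%, 80.6% and 92.4% among 12560 genes, with 11 false calls of 164. With no gene changed it made 0 calls. The changed genes, 67, 67 and 66 in that order, had a mean of at least 1 CPM. Counts were drawn independently per gene and library, so the simulation holds neither genes that vary together nor a library that stands apart from its group. In 20 simulated gene orders, the scan covered all 80 neighbouring genes shifted by 0.4, together with a median of 20 unshifted neighbours, and 2 of the 20 orders gave a window before the shift was added.

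Because strand use is not stated, reads of overlapping genes may not be separable. In GENCODE 29, at least 20% of the exon bases of CTSD, IL6, METTL5, PRDX1, RRM2, SLC9A3 and TUBB6 are shared with another annotated gene, and their values are uncertain for that reason. Values of POTEF, CES1, AKR1B10, AKR1C2, TUBA1C, the histones, the ribosomal proteins and the mitochondrially encoded genes are uncertain because near-identical copies exist elsewhere in the genome. A count of ALKBH5 can come from the endogenous gene or from the vector, and the table does not separate them.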

Results

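Gene expression was profiled in H460/PTX cells, a paclitaxel-resistant non-small cell lung cancer line, carrying either a Control lentivirus (3 libraries) or a lentivirus for overexpression of ALKBH5 (OE-ALKBH5, 3 libraries). ALKBH5 is a demethylase that removes the m6A mark from RNA. Total counts were 27391591, 27709686 and 26397390 in the Control libraries and 22003627, 27693280 and 30097648 in the OE-ALKBH5 libraries. The comparison asked which genes lie downstream of ALKBH5, and the series title names CEMIP and the epithelial-mesenchymal transition.

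ALKBH5 itself was higher in every OE-ALKBH5 library than in every Control library. Its level was 35.2 ± 2.33 CPM (SD, n = 3) in Control and 58.3 ± 2.42 CPM (SD, n = 3) in OE-ALKBH5, a 1.66-fold difference. The log2 fold change was 0.73 with an SE of 0.086 and an adjusted p of 1.94e-05 in edgeR's quasi-likelihood test. CEMIP, listed as KIAA1199 and known for its part in hyaluronan breakdown, fell from 8.76 ± 4.21 CPM to 2.05 ± 0.0565 CPM (SD, n = 3 each). Its log2 fold change was -2.09 with an SE of 0.31 and an adjusted p of 0.0002 in edgeR. The Control libraries differed widely, with 122, 247 and 344 counts, against 45, 55 and 63 counts in OE-ALKBH5, and the groups did not overlap.

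**Figure D1:**
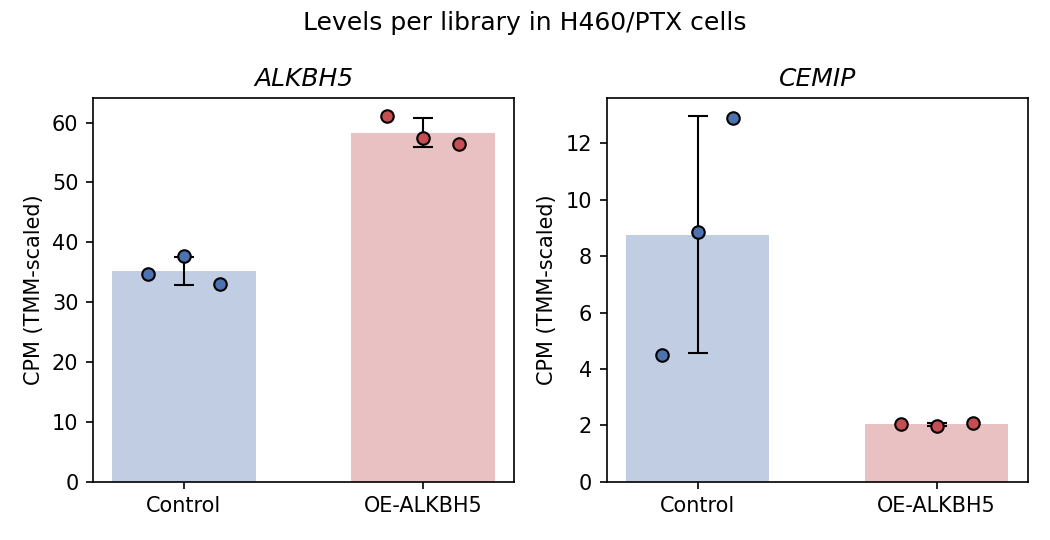
Levels of ALKBH5 (left) and CEMIP (right) in CPM on TMM-scaled library sizes, with points for the 3 Control and 3 OE-ALKBH5 libraries, bars for the group mean and error bars of 1 SD. ALKBH5 averaged 35.2 CPM in Control and 58.3 CPM in OE-ALKBH5, and CEMIP averaged 8.76 and 2.05 CPM.

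Among called genes with a mean of at least 1 CPM over all libraries and no overlap between the groups, the 8 largest changes in each direction were taken. The increases included those of HR, a nuclear corepressor of hair follicle biology, the adhesion molecule NCAM2, the extracellular matrix protein OLFML2A, the junction protein JCAD (listed as KIAA1462) and PLA2G7, which hydrolyses platelet-activating factor. HR rose from 1.43 ± 0.621 to 10.9 ± 0.581 CPM and OLFML2A from 8.69 ± 3.67 to 49.3 ± 4.23 CPM (SD, n = 3 each). The log2 fold changes were 2.92 for HR, 2.74 for TMEM132E, 2.57 for NCAM2, 2.5 for OLFML2A, 2.37 for the sodium-proton exchanger SLC9A3, 2.33 for JCAD, 2.29 for DOC2B and 2.21 for PLA2G7. HR lies in a stretch of chromosome 8 in which 68 of 78 neighbouring genes had values above 0. The decreases included those of CES1, a carboxylesterase, INSYN2B (listed as FAM196B), the gelatinase MMP2 and the adhesion molecule FLRT3. CES1 fell from 84.9 ± 16.7 to 11.4 ± 2.4 CPM and FLRT3 from 31.4 ± 3.96 to 6.15 ± 1.37 CPM (SD, n = 3 each). The log2 fold changes were -2.9 for CES1, -2.78 for INSYN2B, -2.5 for MMP2, -2.34 for FLRT3, -2.24 for POTEF, -2.21 for DHRS2, -2.2 for ADAM28 and -2.19 for MAL2. Adjusted p-values of these 16 genes in edgeR lay between 1.02e-08 for CES1 and 0.0215 for POTEF. TMEM132E, with 0 to 21 counts in Control libraries, lost its call without Control replicate 3 (adjusted p = 0.0755) and without any one OE-ALKBH5 library (0.0764 to 0.0861), was not called by DESeq2 (0.15), and its log2 fold change was 4.73 without Control replicate 1. In edgeR, POTEF was no longer called without Control replicate 3 (adjusted p = 0.193) or without OE-ALKBH5 replicate 1 or 2 (0.103 each) or by limma-voom (0.0596), nor MMP2 without Control replicate 2 (0.0569).

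Over the whole table, 1594 of 12560 tested genes passed the threshold, 827 higher and 767 lower in OE-ALKBH5. Most changes were small, with a median absolute log2 fold change of 0.43 among the called genes, and 107 genes rose and 73 fell by at least 2-fold. Groups did not overlap in 30.8% of tested genes, where chance gives 10%. The first principal component, with 35.2% of the variance, separated the groups. The next one, with 23.5%, separated Control replicate 1 (35.9) from Control replicates 2 and 3 (-22.1 and -14.5) and from the OE-ALKBH5 libraries (-3.8 to 6.3). Without Control replicate 1, edgeR called 2258 genes, 1482 of them shared with the full comparison. Without OE-ALKBH5 replicate 1 it called 866 genes and without OE-ALKBH5 replicate 2 it called 845.

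**Figure D2:**
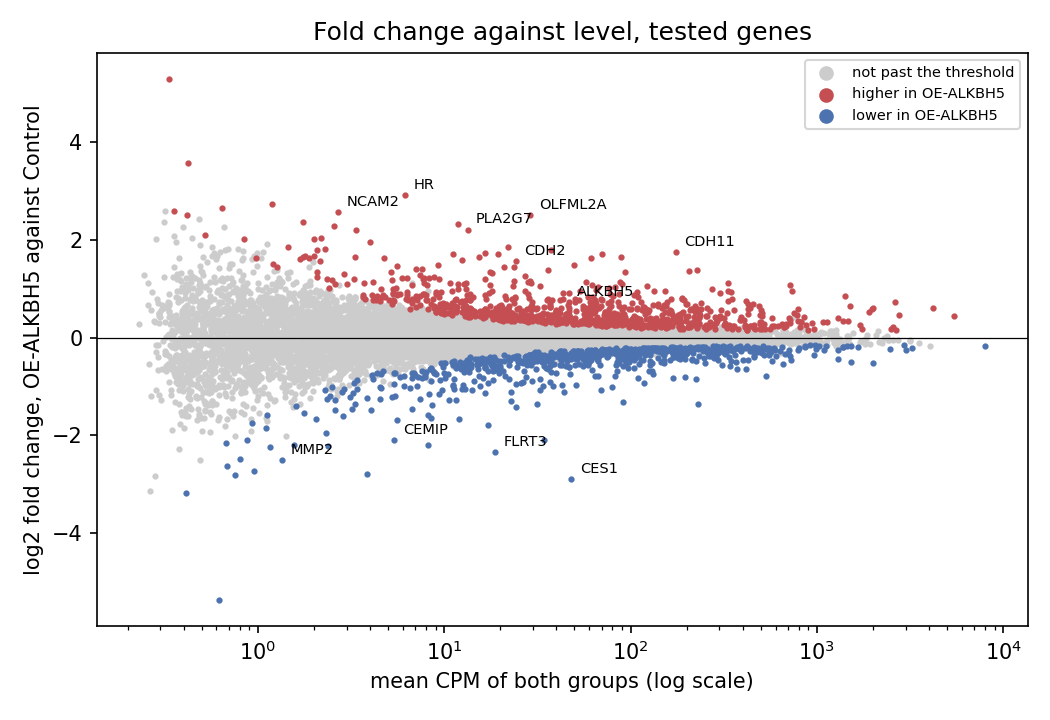
Log2 fold change of OE-ALKBH5 against Control (vertical axis) by mean CPM over both groups (horizontal axis, log scale) for the 12560 tested genes. Genes past the threshold are red where higher (827) and blue where lower (767) in OE-ALKBH5, all others are grey, and some genes named in the text are labelled.

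Mesenchymal markers changed in both directions. Of 40 tested members, 11 rose, 11 fell and 18 did not pass. Adjusted over the list alone, 14 rose and 12 fell. The cadherin CDH11 rose by a log2 fold change of 1.75 (SE 0.11), and N-cadherin, CDH2, rose from 12.3 ± 2.46 to 36.2 ± 1.68 CPM (SD, n = 3 each), a log2 fold change of 1.56. The fibrillar collagen COL5A2 rose by a log2 fold change of 0.61. The collagen COL3A1 had a log2 fold change of -0.82. The share of changed members, 55%, was larger than that of other genes (Fisher's exact test, adjusted p = 5.52e-09), while camera called no shift of the list (adjusted p = 0.816; 0.835 with an estimated correlation). Fry, which does not compare the list with other genes, gave an adjusted p of 0.0405. The list's median was -0.2 and its camera direction was up, so the median and the test differed in sign. Without Control replicate 1 the median was 0.00, and 7 members were lower without Control replicate 2 or without OE-ALKBH5 replicate 1. Chosen after their values were seen, FN1 (fibronectin) had a log2 fold change of 0.61 and SNAI2, which encodes the transcription factor Slug, one of -1.13, both past the threshold in edgeR, and VIM (vimentin) did not pass at 0.07.

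Among 21 tested epithelial markers, 3 rose, 1 fell and 17 did not pass, and adjusted over the list alone 3 rose and 2 fell. The table held 39 markers of this list, and the tested ones did not include E-cadherin, CDH1. Without Control replicate 2 or 3, 2 members were lower. Keratin 19, KRT19, rose from 183.8 ± 12.2 to 364.5 ± 23.2 CPM and the junction protein JUP from 42.6 ± 1.24 to 76.4 ± 6.04 CPM (SD, n = 3 each). DSC2, a desmosomal cadherin, had a log2 fold change of 0.46. Desmoplakin, DSP, fell from 4.27 ± 1.06 to 1.42 ± 0.568 CPM. Camera called no shift of this list (adjusted p = 0.667; 0.835 with an estimated correlation). Of 13 genes of hyaluronan metabolism, 4 rose and 2 fell, and adjusted over the list alone 4 rose and 3 fell. Beside CEMIP, the proteoglycan VCAN had a log2 fold change of -1.03, the hyaluronidase HYAL1 one of 1.2, the link protein HAPLN3 one of 1.11 and CEMIP2 (listed as TMEM2) one of 0.58. VCAN was not called without OE-ALKBH5 replicate 1 or 2 (adjusted p = 0.0869 each in edgeR), nor HAPLN3 without OE-ALKBH5 replicate 2 (0.0651). The list had 2 higher members (CEMIP2 and HYAL1) without OE-ALKBH5 replicate 2, 4 without Control replicate 1 and 3 without any other library, and 1 lower member without OE-ALKBH5 replicate 1 or 2. Camera called no shift of the hyaluronan list (adjusted p = 0.713; 0.835 with an estimated correlation).

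Genes of basement membranes and integrins were higher as a list, with 12 of 30 tested members up, 3 down and a median log2 fold change of 0.15. Adjusted over the list alone, 13 rose and 3 fell. Perlecan, HSPG2, rose from 26.0 ± 1.21 to 73.3 ± 6.72 CPM, dystroglycan, DAG1, from 57.2 ± 5.91 to 93.5 ± 5.83 CPM and the laminin LAMA1 from 1116 ± 79.8 to 1479 ± 56.2 CPM (SD, n = 3 each). The type IV collagen chains COL4A1 and COL4A2 went the other way, with log2 fold changes of -0.99 and -0.6. Of the other type IV collagens on the list, chosen after their values were seen, COL4A3 (0.6) and COL4A4 (0.44) rose and COL4A5 (-0.06) and COL4A6 (0.08) did not pass in edgeR. Camera gave this list an adjusted p of 0.0102, and an adjusted p of 0.508 with an estimated correlation. Control replicate 1 lay below the other Control libraries over this list by a median log2 difference of -0.13, in 21 of 30 members, which is near the size of the shift itself. Without Control replicate 1 the median was 0.11 and the camera adjusted p 0.0267, and without Control replicate 2 the median was 0.24. Without OE-ALKBH5 replicate 1 the list had 5 higher members and without OE-ALKBH5 replicate 2 it had 6. An offset for GC content and transcript length, chosen after seeing the data, raised the adjusted p to 0.11, with a median of 0.13 and 11 members higher and 3 lower.

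**Figure D3:**
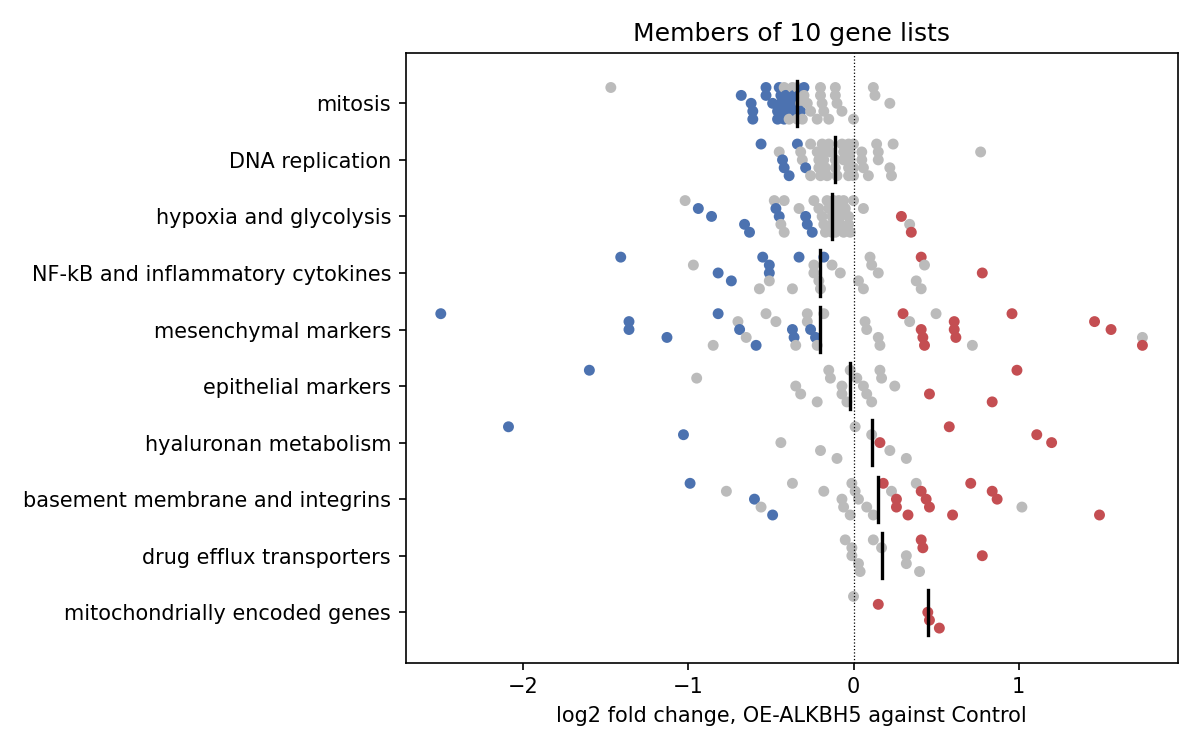
Log2 fold change of OE-ALKBH5 against Control (horizontal axis) for each tested member of 10 gene lists (rows). Red points are higher and blue points lower in OE-ALKBH5 past the threshold, grey points did not pass, and black bars mark list medians, from -0.35 for mitosis to 0.45 for mitochondrially encoded genes.

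Genes of mitosis were lower, with 23 of 48 tested members down, 0 up and 44 below 0. The list's median log2 fold change was -0.35, and adjusted over the list alone 29 members fell. TOP2A, the topoisomerase of dividing cells, fell from 619.8 ± 21.0 to 485.0 ± 13.4 CPM, the kinetochore protein CENPF from 340.8 ± 30.9 to 247.1 ± 17.5 CPM and the spindle protein DLGAP5 from 114.8 ± 8.98 to 82.0 ± 3.02 CPM (SD, n = 3 each). With camera the mitosis list had an adjusted p of 1.63e-12, and an adjusted p of 0.508 with an estimated correlation. In fry its adjusted p was 0.0622. Control replicate 1 lay above the mean of the other Control libraries by a median of 0.27 (log2) over this list, and 22 members were lower without it. Without OE-ALKBH5 replicate 1 or 2, 14 and 13 members were lower. DNA replication genes had 6 of 47 members lower, 0 higher and a median of -0.11, and adjusted over the list alone 6 fell. RRM1 and RRM2, the subunits of ribonucleotide reductase, had log2 fold changes of -0.42 and -0.34, and RFC3, a clamp-loader subunit, one of -0.39. The camera adjusted p of 0.0157 became 0.823 with an estimated correlation. Control replicate 1 lay above the other Control libraries by a median of 0.28 over this list, and without it the list's median was -0.01 and the camera adjusted p 0.466. Without Control replicate 1 the log2 fold change of RRM2 was -0.19. RRM2 was not called without any one OE-ALKBH5 library (adjusted p of 0.0957 to 0.11 in edgeR) or by DESeq2 (0.146), nor RFC3 without OE-ALKBH5 replicate 2 (0.0716). The number of lower replication genes was 2 without OE-ALKBH5 replicate 1, 1 without replicate 2 and 3 without replicate 3.

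Hypoxia and glycolysis genes were lower, with 9 of 45 members down, 2 up, 40 below 0 and a median log2 fold change of -0.13. Adjusted over the list alone, 11 fell and 2 rose. EPAS1, which encodes HIF-2alpha, fell from 490.6 ± 35.1 to 359.4 ± 14.4 CPM, hexokinase HK2 from 260.0 ± 24.5 to 187.4 ± 4.52 CPM and adrenomedullin, ADM, from 23.67 ± 3.68 to 12.96 ± 1.72 CPM (SD, n = 3 each). STC2 was higher, with a log2 fold change of 0.35. The list's camera adjusted p was 2.55e-05, and the adjusted p was 0.589 with an estimated correlation and 0.177 in fry. Control replicate 1 lay below the mean of the other Control libraries by a median log2 difference of -0.28 over this list, in 37 of 45 members. Without it, 29 members were lower and the median was -0.25. The number of lower members was 6 without Control replicate 3 and likewise without OE-ALKBH5 replicate 2 or 3. The number of higher members was 1 without Control replicate 2 and without each of the OE-ALKBH5 libraries.

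In the list of NF-kB and inflammatory cytokine genes, 8 of 28 members fell and 2 rose, with a median log2 fold change of -0.2, and adjusted over the list alone 14 fell and 2 rose. PTGS2, the inducible cyclooxygenase, fell from 35.1 ± 2.65 to 13.2 ± 0.809 CPM, interleukin IL1A from 216.1 ± 24.0 to 122.8 ± 2.82 CPM and the chemokine CXCL5 from 2353 ± 164 to 1652 ± 11.3 CPM (SD, n = 3 each). IL6 rose from 26.2 ± 7.32 to 45.2 ± 2.22 CPM, and TNFAIP3, an inhibitor of NF-kB signalling, had a log2 fold change of 0.41. This list's camera adjusted p was 0.00174, and the adjusted p was 0.484 with an estimated correlation. Apoptosis regulators had 6 members up and 6 down of 33, with the same counts adjusted over the list alone and a camera adjusted p of 0.951 (0.972 with an estimated correlation). The inhibitors of apoptosis BIRC2 and BIRC3 had log2 fold changes of -0.64 and -0.74. The proapoptotic BMF had one of 2.21 and the death receptor TNFRSF10B one of 0.49. TNFRSF10B lies in the same stretch of chromosome 8 as HR.

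Of 13 tested drug efflux transporters, 3 rose and 0 fell, with a median log2 fold change of 0.17, and adjusted over the list alone 4 rose. With 1 library left out, the median ranged from 0.1 (without Control replicate 3) to 0.22 (without OE-ALKBH5 replicate 2). ABCG2 rose from 78.8 ± 9.66 to 104.6 ± 2.89 CPM and ABCA3 from 10.1 ± 1.93 to 17.4 ± 1.79 CPM (SD, n = 3 each). ABCA2, with a log2 fold change of 0.42, had an edgeR adjusted p of 0.0495, which rose above the threshold when any one of Control replicates 2 and 3 and OE-ALKBH5 replicates 1 and 2 was left out (0.0517 to 0.266). It was also not called under other scalings, in limma-voom, with the replicate block, under the GC and length offset or when thinned (0.0511 to 0.131). ABCB1, which encodes P-glycoprotein and was chosen after its values were seen, did not pass (log2 fold change 0.4, edgeR adjusted p = 0.683). Control replicate 1 held 91 counts of it, against 19 and 24 in the other Control libraries and 51, 74 and 46 in OE-ALKBH5. That library thus largely made the difference small, since the other Control libraries lay below every OE-ALKBH5 library. A change of ABCB1 stays open. For the efflux list the camera adjusted p was 0.0304, and the adjusted p was 0.508 with an estimated correlation. Under the GC and length offset the camera adjusted p was 0.11, and with no filter it was 0.0986. Control replicate 1 lay below the other Control libraries by a median of -0.11 over these genes. The camera adjusted p was 0.104 without Control replicate 1, when 5 members rose, and 0.0723 without OE-ALKBH5 replicate 1. Tubulins and microtubule regulators, the targets of paclitaxel and their partners, had 4 of 38 members up and 6 down, with 5 up and 7 down adjusted over the list alone. MAP1A rose from 12.6 ± 0.539 to 34.5 ± 4.49 CPM (SD, n = 3 each), MAP7 had a log2 fold change of 0.53, MAP2 one of -0.45 and TUBA1C one of -0.37. Without OE-ALKBH5 replicate 1 or 2 the list had 3 higher and 3 lower members. Camera called no shift of it (adjusted p = 0.816; 0.931 with an estimated correlation).

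Mitochondrially encoded genes were higher, with 4 of 5 tested members up, a median log2 fold change of 0.45 and the same count adjusted over the list alone. MT-CO3 rose from 2337 ± 75.7 to 3209 ± 80.7 CPM and MT-ND2 from 4581 ± 196 to 6241 ± 333 CPM (SD, n = 3 each). The camera adjusted p was 0.000267, and the adjusted p was 0.484 with an estimated correlation. The table lists 6 mitochondrially encoded genes, and their share of all counts was 0.92% to 0.97% in Control and 1.21% to 1.27% in OE-ALKBH5. Of 26 genes of the m6A machinery, ALKBH5 rose and 4 fell, and adjusted over the list alone 3 rose and 7 fell. The methyltransferase METTL3 fell from 73.6 ± 4.52 to 58.9 ± 0.933 CPM and the m6A reader YTHDC1 from 123.7 ± 15.2 to 99.0 ± 6.6 CPM (SD, n = 3 each). IGF2BP1 had a log2 fold change of -0.7 and METTL5 one of -0.23. None of these 4 decreases was called without OE-ALKBH5 replicate 1 (edgeR adjusted p of 0.0506 to 0.139), and those of IGF2BP1, YTHDC1 and METTL5 were also lost without OE-ALKBH5 replicate 2 (0.0603 to 0.0655). YTHDC1 and METTL5 lost the call without OE-ALKBH5 replicate 3 (0.105 and 0.057), and METTL5 without Control replicate 3 (0.0716), with the replicate block (0.0502) and under the GC and length offset (0.111). The list had 3 higher members without Control replicate 1. It had 2 higher members without OE-ALKBH5 replicate 3, with no filter, in DESeq2 and under the GC and length offset. The other demethylase, FTO, did not pass (log2 fold change 0.3, edgeR adjusted p = 0.0659), nor did METTL14 (-0.12, adjusted p = 0.416) or WTAP (70.0 ± 4.8 and 70.2 ± 2.6 CPM). Camera called no shift of the m6A list (adjusted p = 0.339; 0.835 with an estimated correlation).

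The share of changed members was larger than among other genes in 12 of the 29 lists by Fisher's exact test, unmatched for level. Beside the mesenchymal list these were mitosis (adjusted p = 3.86e-08), basement membrane and integrins (7.73e-06), apoptosis (0.00218), mitochondrially encoded genes (0.00374), NF-kB (0.00459), hyaluronan metabolism (0.00845) and the 5 lists that follow (0.000147 to 0.0212), of which camera called none. Fry called autophagy and lysosome among these 5 (adjusted p = 0.0405). Immediate early and heat shock genes had 8 members up and 7 down of 37, with NR4A1 at a log2 fold change of 1.09, NR4A3 at 0.96, JUN at -0.93 and MYC at -0.5. YAP and TAZ targets had 5 up and 5 down of 26, among them ANKRD1 at -1.31, CCN1 (listed as CYR61) at -0.59 and PTPN14 at 0.41. TGF-beta signalling genes and targets had 6 up and 6 down of 32, with TGFBR1 at 0.52, PMEPA1 at 0.68 and LTBP2 at -0.73. LTBP2 was not called without Control replicate 3 (edgeR adjusted p = 0.0584) or without OE-ALKBH5 replicate 1 or 2 (0.0808 and 0.0618). NRF2 targets had 8 up and 5 down of 38, with the aldo-keto reductase AKR1B10 at 1.37, PGD at 0.5 and ALDH1A1 at -0.46. Autophagy and lysosome genes had 9 up and 3 down of 43, with ULK1 at 0.8 and the cathepsins CTSD and CTSL at 0.63 and 0.44. Adjusted over the list alone, the numbers higher and lower were 8 and 8, 6 and 6, 7 and 9, 11 and 8, and 12 and 3 in the order given. These counts moved with single libraries. Without OE-ALKBH5 replicate 1 or 2, 1 TGF-beta gene was lower, 3 YAP and TAZ targets were higher and 3 lower, and 4 autophagy and lysosome genes were higher. Leaving out Control replicate 3 or OE-ALKBH5 replicate 3 left 2 and 3 lower TGF-beta genes. For YAP and TAZ targets, 3 were higher without Control replicate 2 or 3 or OE-ALKBH5 replicate 3. No autophagy and lysosome gene was lower without OE-ALKBH5 replicate 1 or 3, and 1 was without OE-ALKBH5 replicate 2. NRF2 targets had 13 higher members without Control replicate 1, and 5 higher and 2 lower without OE-ALKBH5 replicate 2. They had 2 lower without Control replicate 2 or OE-ALKBH5 replicate 3, and 3 lower without OE-ALKBH5 replicate 1.

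The remaining lists were not called by camera, while fry called WNT genes and histones (adjusted p = 0.0405 each), and they gave these numbers higher and lower among tested members. They were 0 and 4 of 30 p53 targets, 2 and 2 of 36 interferon response genes, 2 and 2 of 28 WNT genes, 0 and 4 of 27 cholesterol synthesis genes, and 7 and 2 of 41 genes of unfolded protein and amino acid stress. Replication-dependent histones had 2 and 0 of 9, and cytosolic ribosomal proteins 2 and 2 of 76. Adjusted over the list alone, the numbers were 0 and 4, 3 and 4, 3 and 2, 0 and 4, 7 and 2, 2 and 0, and 1 and 2. With 1 library left out, the total of changed members ranged from 0 (without OE-ALKBH5 replicate 3) to 6 (without Control replicate 1 or 2) for p53 targets, 2 (without OE-ALKBH5 replicate 1) to 9 (without Control replicate 1) for interferon genes, 4 to 7 (without Control replicate 1) for WNT genes, and 1 (without OE-ALKBH5 replicate 2) to 4 for cholesterol synthesis. It ranged from 2 (without OE-ALKBH5 replicate 2) to 10 for unfolded protein and amino acid stress and 1 to 9 (without Control replicate 1) for ribosomal proteins, and was 1 for histones whichever library was left out. OAS1, an antiviral enzyme, had a log2 fold change of 0.92, the WNT receptor FZD4 one of 1.12, LGR4 one of 0.65 and ALDH1L2 one of 0.94, each past the threshold in edgeR. DKK1, a secreted WNT inhibitor, was at -1.08, and at -0.58 without Control replicate 1, which held 1906 counts against 907 and 816 in the other Control libraries. Of the markers of other cell types, 1 of 6 lung epithelial and neuroendocrine genes rose (CHGA, log2 fold change 1.22), and COL3A1, also on the mesenchymal list, was the 1 of 5 fibroblast markers that fell. Adjusted over the list alone, each of these 2 lists had 1 higher and 1 lower, and without Control replicate 1 each had 2 lower. None of 2 endothelial markers and the 1 leukocyte marker tested passed, with values of 7.65 ± 1.25 CPM for EGFL7 and 0.589 ± 0.235 CPM for CD14 in OE-ALKBH5 (SD, n = 3 each).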

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

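The GC and length offset and the thinning to the smallest library were chosen after seeing the data. At the adjusted p threshold, ALKBH5 stayed higher and CEMIP lower under the other scalings, filters, tools and corrections and without any one library, with log2 fold changes of 0.68 to 0.78 and -2.41 to -1.71. ALKBH5 fell short of a 2-fold minimum (1.66-fold) and CEMIP did not. The count of 1594 changed genes was 1277 to 1877 under the other scalings, filters, tools and corrections, and 845 to 2258 when 1 library was left out. It was 180 with a 2-fold minimum and 298 with an unadjusted p under 0.05 and a 2-fold minimum. Upper-quartile scaling put the share of higher calls at 45.4% against 51.9%. With the replicate number as a block, 1277 genes were called, 1258 of them shared. Same-numbered libraries did not deviate together (correlations of -0.05, 0.05 and 0.00). These values gave no sign of pairing but cannot exclude it, and the labels state none.

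Of 27 lists, 7 were called with the preset correlation, 0 with an estimated one (adjusted p of 0.484 for NF-kB and mitochondrially encoded genes, 0.508 for mitosis, basement membrane and drug efflux, 0.589 for hypoxia and 0.823 for DNA replication) and 8 by fry. Of those 8, 4 were not called by camera: mesenchymal markers, WNT, autophagy and lysosome, and histones (0.0405 each). Fry did not call mitosis (0.0622), hypoxia (0.177) or DNA replication (0.405). The NF-kB list lost its camera call although its estimated correlation, 0.028, was near the preset 0.01. With 6 libraries that version of camera has little power, so a lost call does not by itself show that members vary together. The GC and length offset ended the calls of basement membrane and drug efflux genes (0.11 each; medians of 0.13 against 0.15 and 0.14 against 0.17), and the lack of a filter that of drug efflux (0.0986). With 1 library left out, the camera adjusted p ranged from 0.0105 to 0.104 for drug efflux (lost without Control replicate 1 or OE-ALKBH5 replicate 1) and from 0.000197 to 0.466 for DNA replication (lost without Control replicate 1), and the other 5 calls held. The cause was not tested.

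Small values that did not pass changed sign. METTL16 was at 0.00076 in limma-voom and 0.00032 with the block, and WTAP at -0.0025 with DESeq2 size factors and in DESeq2, -0.014 with upper-quartile scaling and -0.011 when thinned. With 1 library left out, log2 fold changes ranged from -0.1 to 0.32 for EGFL7, -0.052 to 0.12 for FMR1, -0.1 to 0.15 for METTL16, -0.11 to 0.05 for PRRC2A, -0.036 to 0.14 for RBM15, -0.078 to 0.0035 for VIRMA, -0.052 to 0.051 for WTAP, -0.048 to 0.097 for YTHDF1, -0.035 to 0.11 for YTHDF2 and -0.12 to 0.0098 for ZC3H13. In simulations at these depths, 56.7% of genes with a log2 fold change of 0.5 were recovered, so smaller changes can be missed.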

Other observations

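The tests of annotation terms were chosen after seeing the data, and so were the scan of neighbouring genes, the mitosis gene levels of Control replicate 1 and all 3 tests of the mitosis list. The bounds of the remaining tests were written before their results were seen. Bootstrap intervals in this section resample genes rather than libraries, so they leave out variation between libraries. Among 782 GO processes, camera called 1 higher and 18 lower, and among 224 KEGG pathways 0 higher and 2 lower. With an estimated correlation 0 of these terms were called (adjusted p of 0.908 for the GO and 0.914 for the KEGG terms), and 0 were called without Control replicate 1. The higher process was homophilic cell adhesion, with 14 of 67 tested genes up, 2 down and a median log2 fold change of 0.31 (camera adjusted p = 0.0209; adjusted p = 0.908 with an estimated correlation and 0.0517 in fry). Its changed members, chosen after their values were seen, included the cadherins CDH11 (1.75) and CDH19 (0.4), the protocadherin PCDH7 (1.11) and the immunoglobulin-type adhesion molecule CADM2 (0.58), which rose, and CDH4, which fell (-1.55), each past the threshold in edgeR. The lower terms held mitotic cell cycle (51 of 300 genes lower, 7 higher), RNA splicing (25 of 208 lower, 0 higher) and, in KEGG, ribosome biogenesis (11 of 66 lower, 0 higher).

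In some stretches of the chromosomes, log2 fold changes of neighbouring genes shifted together as blocks. All blocks of the scan, with the 1 not reported here, held 76 of the 1594 changed genes. On chromosome 8, 78 placed genes from ZNF596 to ESCO2 had a median log2 fold change of 0.38, with 68 above 0, 38 called higher and 2 called lower, among them HR, TNFRSF10B and DOCK5. On chromosome 19, 88 genes from ZNF600 to MZF1 had a median of -0.26, with 73 below 0, 21 called lower and 2 called higher. A smaller block passed on chromosome 6 (DDAH2 to HSD17B8, 30 genes, median 0.21, 4 called higher and 1 lower). Over all tested genes, 12.7% were called. With 1 library left out, the medians of the chromosome 8 and chromosome 19 blocks stayed at 0.34 to 0.47 and -0.28 to -0.24. The chromosome 6 median ranged from 0.14 (without Control replicate 1) to 0.26.

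The most extreme windows had medians of 0.59 in the chromosome 8 block and -0.36 in this chromosome 19 block. The blocks were chosen by the scan's own permutations of gene order, so no separate test of chance was made, and shared regulation of neighbours stays open. The GC and length offset left the chromosome 8 median at 0.37 (95% bootstrap interval 0.33 to 0.48) and the chromosome 19 median at -0.26, which argues against a GC or length trend as the whole cause. Zinc finger genes of other chromosomes had a median of 0.06 (0.02 to 0.08), which argues against a decrease of zinc finger genes across all chromosomes. Zinc finger genes of chromosome 19 outside this block were not compared, so a decrease of that chromosome's zinc finger genes stays open. A difference in DNA copy number between the 2 cell populations is one hypothesis, with no test of it here. No DNA was measured, and an effect of ALKBH5 on these regions stays open.

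Control replicate 1 differed from Control replicate 2 by a chi-square of 21.06 per degree of freedom, against 6.01 between replicates 2 and 3. With all libraries thinned to one depth these values were 17.3 and 5.09, and GC content and length together accounted for 5.9% of the variance of its log2 difference from the other Control libraries over 8134 genes, which argues against depth and against a GC or length trend. For genes that differ at least 2-fold between OE-ALKBH5 and Control replicate 3, the shift of Control replicate 1 from Control replicate 2 was taken. It was divided by the gap from Control replicate 3 to OE-ALKBH5. The median share was 16.2% for genes higher in OE-ALKBH5 (95% bootstrap interval 11.7 to 22.6) and 32% for genes lower (21.7 to 41.3). These intervals overlap narrowly. With Control replicates 2 and 3 exchanged the values were 19.1% and 27.9%. Over the chromosome 8 block Control replicate 1 exceeded the other Control libraries by a median log2 difference of 0.14. The difference was -0.03 over the chromosome 19 block, in the direction of OE-ALKBH5 but close in size to the 0.02 between Control replicates 2 and 3. Over the chromosome 6 block it was -0.05, against the direction in OE-ALKBH5, so the blocks do not all agree on this. The shares over 2-fold genes leave open that some cells or RNA like those of OE-ALKBH5 are present. ALKBH5 itself, a single gene, had 943 counts in Control replicate 1, between the 1050 and 881 of replicates 2 and 3. The OE-ALKBH5 libraries held 1342 to 1691 counts of it, so this gene gave no sign of such a mixture. Over the mitosis list, Control replicate 2 lay below replicate 3 by a median of -0.17. That list, lower in OE-ALKBH5, was however higher in Control replicate 1 by a median of 0.27 (0.19 to 0.38), in 41 of 48 members. A mixture with OE-ALKBH5 alone does not give this. A different culture state of that library, in which hypoxia and glycolysis genes were also lower by a median of -0.28, stays open and was not tested.

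The lower mitosis genes did not rest on Control replicate 1 alone, since 22 were called lower without it. The list's median then shrank from -0.35 to -0.28, while calls over all genes rose from 1594 to 2258. The GO process mitotic cell cycle lost its camera call without that library (adjusted p = 0.208). Nor did the lower mitosis genes rest on GC content or length alone, since 25 were called lower under the offset. The median of the DNA replication genes lay 0.24 above that of the mitosis genes (log2, 95% bootstrap interval over genes 0.15 to 0.33). That interval takes genes as independent, but their estimated correlations were 0.326 for replication and 0.379 for mitosis, so it is too narrow. With 1 library left out, the medians ranged from -0.44 to -0.28 for mitosis and from -0.18 to -0.01 for replication. In these libraries this argues only against a loss of cycling cells that lowers both lists alike, with the spread between cultures left unmeasured. A loss of cycling cells that lowers mitosis genes more than replication genes would leave such a gap too, and stays open. A change within the mitotic part of the cycle is one hypothesis, with no test of it here. The loss of the call with an estimated correlation (adjusted p = 0.508) leaves open that genes of this list vary together between cultures.

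The 10 ways to split the 6 libraries into 3 and 3 are too few for a share under 0.05. The real split gave 1594 genes in edgeR, 1 of 10 splits with as many, and the highest other split gave 0 (516 genes at an unadjusted p under 0.05, against 3252 in the real split). Every other split puts libraries of both groups on each side, so a group difference widens its spread and lowers its calls. These splits therefore do not show how many genes would be called between libraries of like cells. The other splits were run in edgeR only.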
